A study of Mus musculus with 12 samples.

How the data were processed

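Expression was measured in the liver of 12 C57Bl/6J mice, 6 given an adenovirus with a scrambled short hairpin RNA and 6 given an adenovirus with a short hairpin RNA against Grb14. Per the labels' protocols, total RNA was extracted with Trizol, and 100 ng of it was labelled with biotin for Affymetrix whole-transcript arrays, 1 array per mouse. The deposited table holds log2 expression values for 35556 probe sets on each of the 12 arrays. RMA, a method that corrects background, normalises and summarises the probes of a probe set, and the software Partek are both named in the submitters' processing notes, with no version, role or order. The chip description file, the settings and the genome build of the probes were not given in the sources used here, so no coordinates are printed. The deposited values lay between 2.742 and 14.24, and the array medians between 7.06 and 7.17. Values near the top of this scale can be compressed, which was not tested here, so changes of the brightest genes can be understated. The same holds for genes near the bottom of the scale, for which no detection call was made. Scan dates and hybridisation batches are not given in the labels, so no batch could be tested, and any batch that followed the groups could not be told apart from them.

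Probe sets were named through the platform's gene annotation. Of the probe sets, 21789 had 1 gene symbol, 1621 had several symbols and 12146 had no listed gene. The Entrez identifiers of 21698 probe sets matched a RefSeq gene table of GRCm38.p6, which was used for names alone, and 0 symbols changed. Probe sets with several symbols or no listed gene were left out of the gene tests. For the 999 genes with several probe sets, the probe set with the highest mean over all 12 arrays was used, and 18939 genes had 1 probe set. Probe sets of the same gene passed the test in opposite directions for 21 genes, none of them named in the text. Probe sets of gene families with near-identical copies, such as Cyp2c, Mup, Ces, Ugt, Sult and Gstm genes, can hybridise with transcripts of related genes, so values of their single members are uncertain in that respect.

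The 19938 genes were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with all 12 arrays in the fit, no covariate and no filter on intensity. A gene passed the test when its Benjamini-Hochberg adjusted p over all genes tested was under 0.05. Changes are log2 differences, sh Grb14 minus sh scramble, with the standard error (SE) of the fit. Group levels are means with the standard deviation (SD) over 6 mice. For Grb14, a two-sided exact permutation test over all assignments of the mice to 2 groups of 6 was run as well. Each of the 2 groups had 6 arrays, and this number limits the precision.

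Gene lists were tested with the mean of the measured members in each mouse. The difference of the group means was compared with all such assignments in a two-sided exact permutation test, whose smallest possible p is 0.00216, and p was adjusted within 20 pathway lists and within 19 cell type lists. A list was called shifted when this adjusted exact p was under 0.05. The pathway lists were insulin signalling components, fatty acid and triglyceride synthesis, gluconeogenesis and amino acid catabolism, glycolysis and glycogen, LXR targets, NRF2 targets, autophagy, cholesterol synthesis and uptake, fatty acid oxidation and PPAR-alpha targets, bile acid synthesis and transport, cytochrome P450 drug metabolism, interferon response, antigen processing and presentation, acute phase proteins, inflammatory cytokines and NF-kB targets, endoplasmic reticulum stress and ATF4 targets, cell cycle, p53 targets, mitochondrial oxidative phosphorylation, and circadian clock. The lists for cell types, neighbouring tissue and handling were hepatocyte secreted proteins, periportal hepatocytes, pericentral hepatocytes, Kupffer cells, monocytes and recruited macrophages, neutrophils, dendritic cells, T cells, NK and cytotoxic cells, B and plasma cells, liver sinusoidal endothelial cells, stellate cells and fibroblasts, cholangiocytes, erythroid cells, adipocytes, pancreatic acinar cells, male-biased liver genes, female-biased liver genes, and immediate early genes. Some genes stand in more than 1 list. Because so many genes differed, 75% of 1000 random lists of 20 genes also had an exact p under 0.05. Each list's median change was therefore also placed among those of 10000 random lists of the same size, drawn gene by gene within 250 ranks of the members' mean level, and the percentile is given. Draws past the end of the ranking took its last gene, so lists at the top of the scale, such as hepatocyte secreted proteins, were matched less well. The draws also take genes independently, so a list of correlated genes can reach an extreme percentile without a shift. A competitive test, camera, was run as an alternative with a preset correlation between genes of 0.01 and with an estimated correlation.

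The groups, tests, lists and alternatives and the rule for named genes were chosen before the data were examined. Under that rule the text names 15 genes of interest (1 more is not reported here), the 10 largest rises and 10 largest falls among genes past the test, leaving out predicted or unnamed models, small RNA, olfactory and vomeronasal genes, and the members with the smallest p in each list with a member past the test. The rule allowed 2 members per list and up to 4 where the list shifted; 3 for shifted pathway lists and 2 for the others were settled on after a first look at the values. Other genes and 16 gene families named later were chosen after their values were seen, as stated where they appear.

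The alternatives were quantile normalization of the deposited table, centring of each array on its median of the tested genes, only the genes above the median of mean level, the mean of a gene's probe sets, every probe set tested on its own, eBayes without a trend, eBayes with a trend and robust estimation, array weights, each mouse left out in turn, and camera for the lists. Single mice were compared with the others of their group by Dixon's test (critical value 0.625 for 6 mice). The gene test was tested on simulated data for this comparison over 19938 genes, of which 200 were changed: it recovered 96% of genes raised 1.5-fold, 98% raised 2-fold, 100% raised 4-fold and 100% lowered 2-fold, and called 10 of 19738 unchanged genes. In the simulation, 6.5% of unchanged lists had an exact p under 0.05. It drew noise independently for each gene and changed a far smaller share of genes than the 65.3% that passed in the data. It therefore does not test the setting of many changed and correlated genes.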

Results

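The data are liver expression profiles of 12 C57Bl/6J mice, an inbred laboratory strain. At 10 weeks of age, 6 mice received by vein an adenovirus carrying a scrambled short hairpin RNA (sh scramble), which has no intended target, and 6 received one carrying a short hairpin RNA against Grb14 (sh Grb14). The livers were taken from fed animals 7 days later, and each gave 1 array. Grb14 is an adapter protein that binds the activated insulin receptor and inhibits it, and the comparison asks how liver expression differs when it is reduced. Each array holds log2 RMA values for 35556 probe sets, with array medians between 7.06 and 7.17. Across genes, which are not independent replicates, 2 arrays of the same group correlated with r between 0.990 and 0.997, and 2 arrays of different groups with r between 0.959 and 0.972. The first principal component held 84.8% of the variance and separated the groups. Livers without virus were not analysed here.

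Grb14 fell in all 6 sh Grb14 livers. Its log2 level, from probe set 10483163, was 10.15 ± 0.063 (SD, n = 6) in sh scramble livers and 8.24 ± 0.13 (SD, n = 6) in sh Grb14 livers, with ranges of 10.08 to 10.25 and 8.02 to 8.44. The change was −1.91 (SE 0.059), 3.75-fold lower, which left 26.7% of the sh scramble level (limma adjusted p = 7.99e-14; exact permutation p = 0.00216, the smallest that the assignments of 12 mice to 2 groups of 6 can give).

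Among the other genes of interest, the insulin receptor gene and Irs2 fell while genes of the antioxidant response rose. Insr, the insulin receptor, fell by 1.09 (SE 0.041), from 11.35 to 10.26. Irs2, an insulin receptor substrate, fell by 0.71 (SE 0.098), whereas Irs1 had a change of −0.062 (SE 0.061) that did not pass the test (limma adjusted p = 0.375). Centring each array on its median moved Irs1 to −0.21 (adjusted p = 0.00282; range over all alternatives 0.00282 to 0.732). Nfe2l2, which encodes the antioxidant regulator NRF2, rose by 1.04 (SE 0.046), and its target Nqo1 rose 7.82-fold (log2 2.97, SE 0.12). Gclc, needed for glutathione synthesis, rose by 0.81 (SE 0.042), Gstm3, a glutathione transferase, by 1.18 (SE 0.058), and Sqstm1, an autophagy receptor, by 0.31 (SE 0.033). Srebf1, a regulator of fat synthesis, fell by 1.02 (SE 0.076), its target Fasn, the fatty acid synthase, by 1.30 (SE 0.13), and Scd1, a fatty acid desaturase, by 0.56 (SE 0.070). Nr1h3, the nuclear receptor LXR-alpha, fell by 0.17 (SE 0.045). The gluconeogenic genes Pck1 and G6pc fell by 0.80 (SE 0.16) and 0.81 (SE 0.13).

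**Figure D1:**
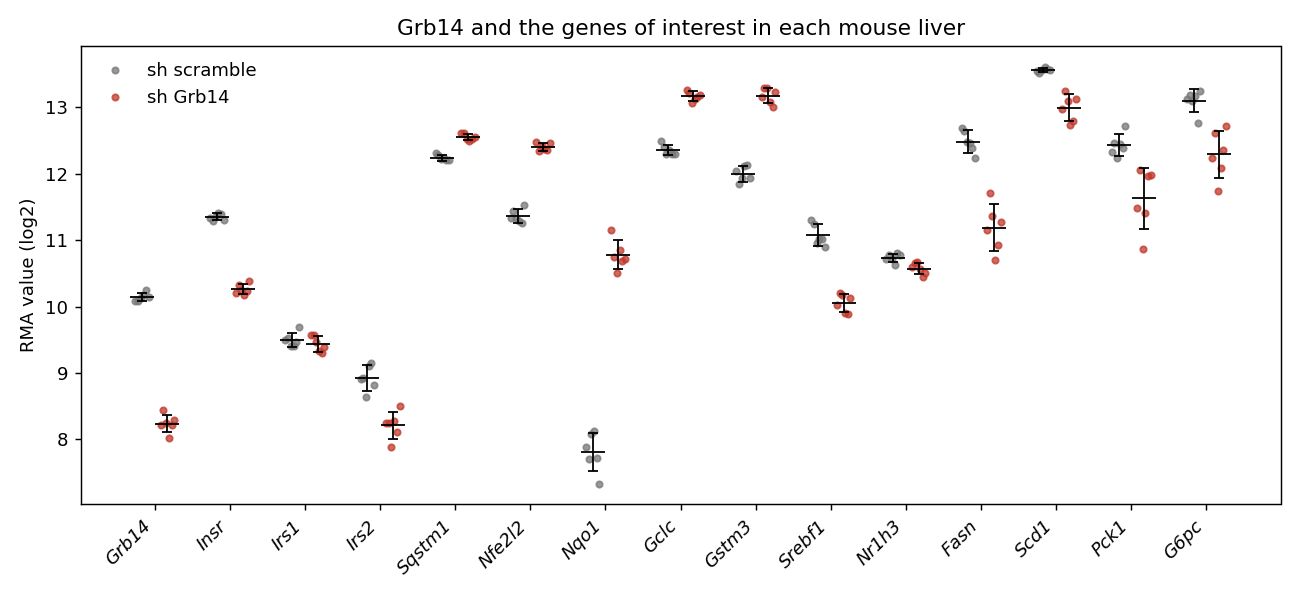
Log2 RMA value (vertical axis) of Grb14 and the other genes of interest in each liver, grey for sh scramble and red for sh Grb14, with the mean and SD of 6 mice as bars. Grb14 sits between 10.08 and 10.25 in sh scramble livers and between 8.02 and 8.44 in sh Grb14 livers, and Irs1 is the gene whose change did not pass the test.

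The difference between the groups reached far beyond these genes. Of 19938 genes tested, 13012 (65.3%) passed, 5144 higher and 7868 lower in sh Grb14 livers. Among the 9969 genes above the median of mean level, 48.5% of those past the test were higher, and the median change was −0.02. The excess of falls therefore lay mostly among the dimmer genes, for which no detection call was made. Larger changes were more often rises: 3742 genes changed at least 1.5-fold (2294 higher, 1448 lower), 1800 at least 2-fold (1271 higher, 529 lower) and 404 at least 4-fold (315 higher, 89 lower). The groups did not overlap in 8205 genes (41.2%), against 0.216% by chance. The median change of all genes was −0.10, and centring each array on its median moved it to −0.25, which lowered the share of higher genes among those past the test from 39.5% to 23%. Small changes near these medians, such as that of Irs1, therefore depend on the scaling.

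The largest rises included the fetal liver genes Afp and Gpc3, the cornified envelope gene Sprr1a and the macrophage gene Gpnmb. Sult1e1, an oestrogen sulfotransferase, rose from a log2 level of 4.49 to 10. Afp, the fetal serum protein alpha-fetoprotein, rose 36.9-fold, from a log2 level of 6.80 ± 0.23 to 12 ± 0.54 (SD, n = 6 each), and Gpc3, a surface proteoglycan of fetal liver, rose by 4.49 (SE 0.15). Sprr1a, a cornified envelope protein also seen after injury, rose by 5.10 (SE 0.097), the transcription factor gene Mybl1 by 5.04 (SE 0.12), and Gpnmb, a glycoprotein of lipid-laden macrophages, by 4.79 (SE 0.15). Ly6d rose by 4.6 and the defensin Defb1 by 4.44. The cystine transporter Slc7a11 went from 5.29 to 9.78 and the peptide hormone gene Apela from 4.58 to 8.92. The sh scramble levels of Sult1e1, Slc7a11 and Apela lie below the lower quartiles of those arrays (5.69 to 5.83), and no detection call was made, so their changes can be understated and no fold is given.

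The largest falls included transporter, steroid and drug metabolism genes. Slco1a1, an organic anion transporter, fell by 6.19 (73.3-fold lower, SE 0.17), and the steroid enzyme gene Hsd3b5 fell by 6.04 (65.7-fold lower, SE 0.12). The sh Grb14 levels of Slco1a1, Hsd3b5 and Mup21 (6.09, 6.22 and 5.84) lie near the lower quartiles of those arrays (5.69 to 5.78), so their falls can be understated. The sulfotransferase Sult2a8 fell by 5.69 (SE 0.15), the carboxylesterase Ces3b fell by 4.89 (SE 0.12), and the pseudogene Serpina4-ps1 fell by 4.55 (SE 0.19). Cyp2c54, a cytochrome P450, fell by 4.51, Mup21, a major urinary protein, fell by 4.15, and Elovl3, a fatty acid elongase, fell by 3.96. Obp2a fell by 3.77 and the UDP-glycosyltransferase Ugt3a1 fell by 3.62. All 20 of these changes passed limma's test with each group non-overlapping (exact permutation p = 0.00216 for each gene). Sult2a8, Ces3b, Cyp2c54, Mup21 and Ugt3a1 belong to families of similar genes and may share signal with relatives on the array.

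The gene lists were compared next. By the exact permutation test, 17 of 20 pathway lists and 15 of 19 cell type lists shifted, and for lists at the smallest p the adjusted exact p was 0.00271 (pathways) or 0.00294 (cell types). This test alone does not set a list apart from the rest of the genes, since 75% of random lists of 20 genes also had an exact p under 0.05. With camera and a preset correlation, 14 pathway lists and 13 cell type lists stood apart from other genes, and with an estimated correlation 0 and 1 did. The number of members past the test adjusted over the list alone was the same as over all genes for 36 of the 39 lists, and it is given below for the others.

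Insulin signalling components moved both ways. Grb7, an adapter of the same family as Grb14, fell 2.63-fold (log2 −1.40, SE 0.083), Insr fell as above, and Ptpn1, a phosphatase that acts on the insulin receptor, rose by 0.96 (SE 0.059). Of 23 measured members 9 rose, 12 fell and 2 did not pass (22 past the test adjusted over the list alone). The mean shift was small, −0.061 (adjusted exact p = 0.0178; adjusted p = 0.960 with an estimated correlation), and the median of −0.12 lay at percentile 27.9 of matched random lists.

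Genes of glucose production and glycogen fell, in livers where markers of recruited macrophages and T cells shifted by 2.06 and 1.35. Periportal and pericentral hepatocyte genes shifted by −0.86 and −0.89 there. Hepatocyte secreted protein genes, near the top of the scale where changes can be compressed, shifted by −0.29. Hal, the first enzyme of histidine breakdown, fell 4.10-fold (log2 −2.04, SE 0.13), Slc37a4, the glucose 6-phosphate transporter, fell by 1.22 (SE 0.066), and Tdo2, which opens tryptophan breakdown, by 0.56 (SE 0.045). In the gluconeogenesis and amino acid catabolism list 11 of 13 measured genes fell, 1 rose and 1 did not pass. Its mean shift was −0.57 and its median percentile 0.330 (adjusted exact p = 0.00271; adjusted p = 0.302 with an estimated correlation). Ppp1r3b, a subunit that directs phosphatase to glycogen, fell 4.45-fold (log2 −2.15, SE 0.080), and Pygl, the liver glycogen phosphorylase, fell by 0.94 (SE 0.055), whereas Pgm2 rose by 1.41 (SE 0.051). The glycolysis and glycogen list had 7 genes lower, 2 higher and 2 not past the test, a mean shift of −0.57 and percentile 0.350 (adjusted exact p = 0.00271). With camera its adjusted p was 0.0532 at the preset correlation and 0.325 with an estimated correlation.

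Genes of fat and cholesterol synthesis fell together. Thrsp, a lipogenic regulator, fell 7.70-fold (log2 −2.94, SE 0.11), Acss2, which makes acetyl-CoA from acetate, fell by 1.85 (SE 0.078), and Fads1, a desaturase, by 1.22 (SE 0.055). Of 22 genes of fatty acid and triglyceride synthesis 21 fell and 1 rose, with a mean shift of −0.98 and percentile 0 (adjusted exact p = 0.00271; adjusted p = 0.167 with an estimated correlation). All 16 measured genes of cholesterol synthesis and uptake fell, with a median change of −1.47, a mean shift of −1.33 and percentile 0 (adjusted exact p = 0.00271; adjusted p = 0.148 with an estimated correlation). Among them Stard4, a sterol transfer protein, fell by 1.98 (SE 0.070), and the mevalonate pathway genes Pmvk and Fdps fell by 1.82 (SE 0.069) and 1.69 (SE 0.065). In the same livers periportal and pericentral hepatocyte genes shifted by −0.86 and −0.89 and markers of monocytes and recruited macrophages by 2.06. Hepatocyte secreted protein genes, near the top of the scale where changes can be compressed, shifted by −0.29.

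**Figure D2:**
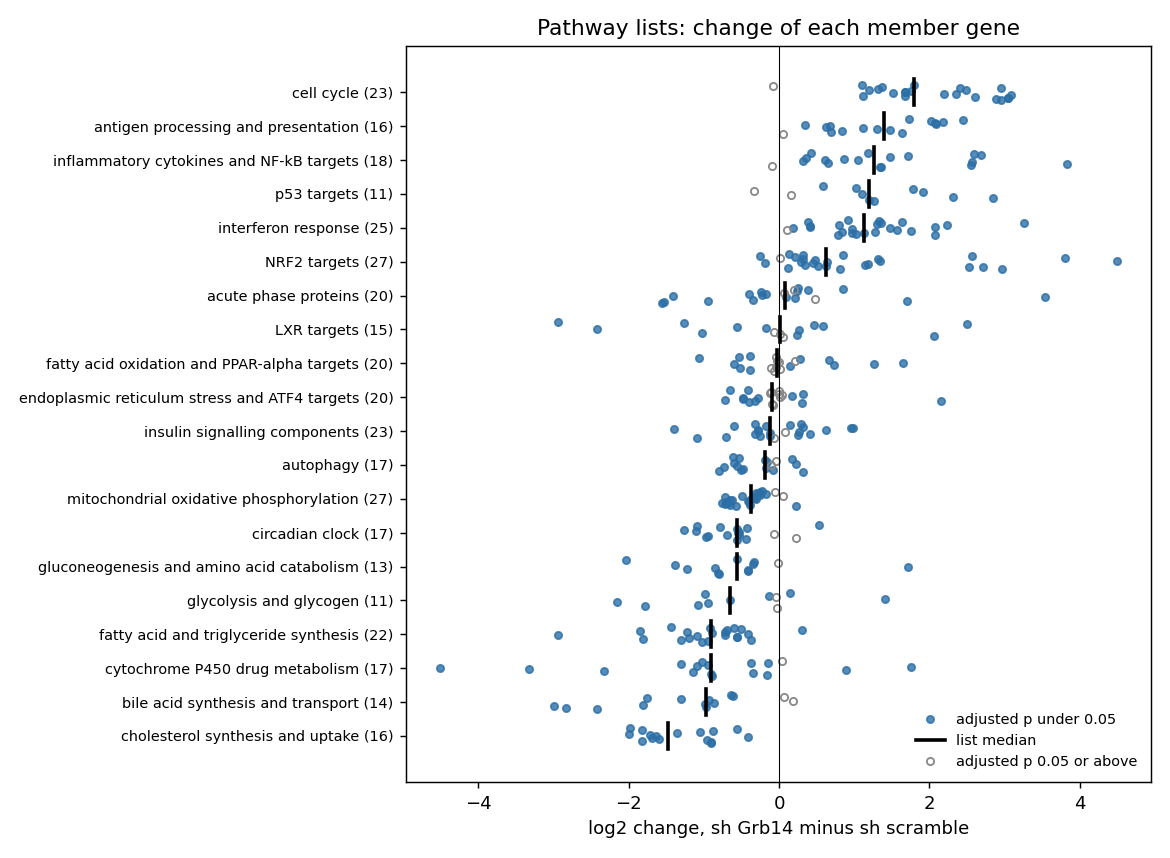
Log2 change, sh Grb14 minus sh scramble (horizontal axis), of each measured member (points) of the 20 pathway lists (rows, with the number of measured genes), with filled points for adjusted p under 0.05, open points for the others, and a black bar at the list median. Medians run from 1.80 for cell cycle to −1.47 for cholesterol synthesis and uptake.

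LXR targets split. Lpl, lipoprotein lipase, rose 5.67-fold (log2 2.5, SE 0.13) and Abcg1, a cholesterol exporter, rose by 2.06 (SE 0.060), while Thrsp fell as above. Among 15 measured targets 6 rose, 6 fell and 3 did not pass. The mean shift was −0.15 with a median of 0.0089, and camera ranked the list upward, so mean, median and competitive test differed in sign (adjusted exact p = 0.00271; adjusted p = 0.922 with an estimated correlation; percentile 80.1).

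Bile acid genes fell, beside shifts of −0.86 and −0.89 in periportal and pericentral hepatocyte genes and 2.06 in markers of recruited macrophages. Hepatocyte secreted protein genes, near the top of the scale where changes can be compressed, shifted by −0.29. Cyp7b1, of the alternative synthesis pathway, fell 7.96-fold (log2 −2.99, SE 0.12), Slc27a5, a bile acid CoA ligase, fell by 1.75 (SE 0.065), and Cyp27a1, the sterol 27-hydroxylase, by 0.97 (SE 0.045). Of 14 measured genes 12 fell and 2 did not pass, with a mean shift of −1.27 and percentile 0.01 (adjusted exact p = 0.00271; adjusted p = 0.163 with an estimated correlation). Fatty acid oxidation and PPAR-alpha targets did not shift as a list. There 6 of 20 measured genes rose, 6 fell and 8 did not pass, and the mean (0.059) and median (−0.032) differed in sign (adjusted exact p = 0.166, percentile 75.6). Ppara itself fell by 1.06 (SE 0.048), and Acadvl, a long-chain acyl-CoA dehydrogenase, fell by 0.52 (SE 0.036).

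Targets of NRF2 rose with the gene that encodes it, in livers where markers of monocytes and recruited macrophages shifted by 2.06 and those of Kupffer cells by 0.89. Cbr3, a carbonyl reductase, rose 13.9-fold (log2 3.80, SE 0.11), Hmox1, heme oxygenase 1, rose 6.52-fold (log2 2.71, SE 0.061), and Srxn1, sulfiredoxin, rose by 2.53 (SE 0.061). Of 27 measured targets 24 rose, 2 fell and 1 did not pass, with a mean shift of 1.10 and percentile 100 (adjusted exact p = 0.00271; adjusted p = 0.0879 with an estimated correlation). Autophagy genes other than Sqstm1 mostly fell. Map1lc3a, an LC3 protein of the autophagosome, fell by 0.80 (SE 0.057), Atg3 by 0.73 (SE 0.045) and Gabarapl2 by 0.48 (SE 0.034). Of 17 measured genes 12 fell, 3 rose and 2 did not pass (16 past the test adjusted over the list alone), with a mean shift of −0.29 (adjusted exact p = 0.00271; adjusted p = 0.308 with an estimated correlation), and the median lay at percentile 16.8, within the range of random lists.

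Drug-metabolising genes fell, and stress genes of the endoplasmic reticulum moved little. In the same livers periportal and pericentral hepatocyte genes shifted by −0.86 and −0.89 and markers of recruited macrophages by 2.06. Cyp2c54 fell as above, Cyp2c37 fell by 2.33 (SE 0.11), and Cyp2e1, the ethanol-oxidising P450, fell from 13.54 to 12.61, a change of −0.94 (SE 0.041). In the cytochrome P450 list 14 of 17 measured genes fell, 2 rose and 1 did not pass, with a mean shift of −0.93 and percentile 0 (adjusted exact p = 0.00271; adjusted p = 0.302 with an estimated correlation). In the endoplasmic reticulum stress and ATF4 list 4 of 20 genes rose, 8 fell and 8 did not pass, with the median at percentile 36.2. The mean shift of −0.058 did not pass (adjusted exact p = 0.0722), although it did under 7 alternatives (adjusted exact p 0.00241 to 0.0337), the lowest with arrays centred on their medians and 2 of them with 1 mouse left out, sh scramble 3 or sh Grb14 1. Atf3, a stress-induced transcription factor, rose by 2.16 (SE 0.096), and Sel1l, a component of protein degradation at this organelle, fell by 0.66 (SE 0.039).

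Proliferation genes rose. Ccnb2, a mitotic cyclin, rose 8.22-fold (log2 3.04, SE 0.078), Mki67, the proliferation marker Ki-67, rose 7.70-fold (log2 2.95, SE 0.077), and the spindle checkpoint gene Bub1b rose by 2.20 (SE 0.061). Of 23 measured cell cycle genes 22 rose and 1 did not pass. The median change was 1.80, the mean shift 2.0 and the percentile 100 (adjusted exact p = 0.00271; adjusted p = 0.0619 with an estimated correlation). Markers of T cells, cytotoxic cells and macrophages, cell types that can proliferate in the liver, rose in the same livers, with mean shifts of 1.35, 1.39 and 2.06.

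Genes induced by p53 and immediate early genes rose as well. Markers of recruited macrophages, T cells and cytotoxic cells shifted by 2.06, 1.35 and 1.39 in these livers. Periportal and pericentral hepatocyte genes shifted by −0.86 and −0.89. Phlda3 rose 7.22-fold (log2 2.85, SE 0.070), the receptor gene Eda2r rose by 2.31 (SE 0.081), and Mdm2, the ubiquitin ligase that restrains p53, rose by 1.26 (SE 0.050). Of 11 measured p53 targets 9 rose and 2 did not pass (10 past the test adjusted over the list alone), with a mean shift of 1.26 and percentile 100 (adjusted exact p = 0.00271; adjusted p = 0.0724 with an estimated correlation). Among immediate early genes, which respond within minutes to stimuli and to handling of tissue, Klf6 rose by 2.58 (SE 0.061) and Egr2 by 1.71 (SE 0.067). That list had 11 of 14 genes higher and 3 not past the test, with a mean shift of 1.13 and percentile 99.99 (adjusted exact p = 0.00294; adjusted p = 0.0530 with an estimated correlation).

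Interferon-induced and antigen presentation genes rose. Gbp3, an interferon-induced GTPase, rose 4.68-fold (log2 2.23, SE 0.066), Ifit2 rose by 2.07 (SE 0.079), and Usp18, which restrains interferon signalling, by 1.47 (SE 0.056). Of 25 measured interferon response genes 24 rose and 1 did not pass, with a mean shift of 1.21 and percentile 100 (adjusted exact p = 0.00271; adjusted p = 0.0946 with an estimated correlation). H2-DMa, of class II presentation, rose 5.45-fold (log2 2.45, SE 0.084), the class II regulator Ciita rose by 1.73 (SE 0.065), and the peptide transporter Tap1 by 1.64 (SE 0.049). Of 16 measured presentation genes 15 rose and 1 did not pass, with a mean shift of 1.33 and percentile 100 (adjusted exact p = 0.00271; adjusted p = 0.0808 with an estimated correlation). Dendritic cell and macrophage markers, from cells that carry class II molecules, shifted by 0.81 and 2.06 in the same livers.

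Inflammatory genes rose, and acute phase proteins moved both ways. The chemokine genes Ccl3 and Ccl2 rose 14.2-fold (log2 3.83, SE 0.078) and 5.86-fold (log2 2.55, SE 0.069), and Vcam1, a leukocyte adhesion molecule, rose by 2.69 (SE 0.076). Of 18 measured inflammatory cytokines and NF-kB targets 17 rose and 1 did not pass, with a mean shift of 1.42 and percentile 100 (adjusted exact p = 0.00271; adjusted p = 0.0619 with an estimated correlation). Leukocyte markers rose in the same livers. Of 20 acute phase genes 8 rose, 9 fell and 3 did not pass. The mean shift of 0.059 did not pass (adjusted exact p = 0.608), although the median lay at percentile 99.06. Lcn2, lipocalin 2, rose 11.6-fold (log2 3.54, SE 0.13), and Crp, C-reactive protein, fell by 1.41 (SE 0.087).

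Markers of myeloid cells rose. Gpnmb and Cd68, a lysosomal protein of macrophages, rose by 4.79 and 1.94 (SE 0.065), and all 11 measured genes of monocytes and recruited macrophages rose, with a mean shift of 2.06 (adjusted p = 0.0530 with an estimated correlation). Of 12 Kupffer cell markers 8 rose and 4 did not pass (mean shift 0.89; 0.141 with an estimated correlation), and among them Cd5l rose by 1.79 (SE 0.079) and the complement gene C1qc by 1.59 (SE 0.072). In neutrophils 8 of 11 markers rose and 3 did not pass (mean shift 1.24; adjusted p = 0.136 with an estimated correlation). The chemokine receptor Cxcr2 rose by 2.36 (SE 0.11) and Mmp8 by 1.66 (SE 0.088). Their sh scramble levels (5.22 and 5.64) lie below the lower quartiles of those arrays, so both changes can be understated. In dendritic cells 5 of 9 rose and 4 did not pass (mean shift 0.81; adjusted p = 0.141 with an estimated correlation), Itgax by 2.41 (SE 0.080) and Clec9a by 2.23 (SE 0.10). The adjusted exact p was 0.00294 for each of these lists. The percentile was 100 for each but dendritic cells, at 88.7.

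Markers of T and cytotoxic cells rose too. Gzmb, granzyme B, rose 11-fold (log2 3.46, SE 0.087) and Nkg7 rose by 3.24 (SE 0.088). Of 14 NK and cytotoxic cell genes 11 rose and 3 did not pass, with a mean shift of 1.39, and this list kept its call with an estimated correlation (adjusted p = 0.0412). In T cells 12 of 13 measured genes rose, among them Cd3g by 2.95 (SE 0.076) and Cd8b1 by 2.05 (SE 0.072), and 1 fell. That gene, named after its value was seen, was Cd4, at −0.66 (SE 0.053). The T cell list shifted by 1.35 (adjusted p = 0.136 with an estimated correlation), and both lists had an adjusted exact p of 0.00294 and percentile 100. B and plasma cell markers shifted by 0.15 (adjusted exact p = 0.0356; adjusted p = 0.703 with an estimated correlation; percentile 99.6), with 5 of 9 higher, 1 lower and 3 not past the test. Cd22 rose by 0.67 (SE 0.084) and Ms4a1, whose sh scramble level of 5.635 lies below the lower quartiles of those arrays, by 0.39 (SE 0.068). This call ended when arrays were centred on their medians (0.0068, adjusted exact p = 0.894) and without any 1 of 6 mice, sh scramble 3, 4 or 5 or sh Grb14 2, 4 or 5 (adjusted exact p 0.0565 to 0.0685).

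Markers of hepatocytes fell. The secreted proteins Apoa2, an apolipoprotein, and F2, prothrombin, fell by 0.98 (SE 0.049) and 0.43 (SE 0.038), and 12 of 15 genes of hepatocyte secreted proteins fell with 3 not past the test (mean shift −0.29; percentile 1.43; adjusted p = 0.414 with an estimated correlation). Genes of both lobular zones fell as well. Around the portal vein 7 of 9 measured genes fell, 1 rose and 1 did not pass (mean shift −0.86; percentile 0.100; adjusted p = 0.414 with an estimated correlation), among them Hal, given above, and the urea cycle gene Asl by 1.25 (SE 0.077). Around the central vein 9 of 12 fell, 1 rose and 2 did not pass (mean shift −0.89; percentile 0; adjusted p = 0.136 with an estimated correlation), among them Cyp2e1, given above, and Rgn, regucalcin, by 2.77 (SE 0.12). All 3 lists had an adjusted exact p of 0.00294.

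Stromal and duct markers rose. Timp1, an inhibitor of matrix proteases, rose 7.17-fold (log2 2.84, SE 0.11), and Col1a1, a chain of collagen I, rose by 1.76 (SE 0.066). Of 14 genes of stellate cells and fibroblasts 10 rose, 2 fell and 2 did not pass (mean shift 1.11; percentile 100; adjusted exact p = 0.00294; adjusted p = 0.214 with an estimated correlation). Of 9 measured cholangiocyte genes 5 rose and 4 did not pass (mean shift 0.49; percentile 97.49; adjusted exact p = 0.00294; adjusted p = 0.233 with an estimated correlation), Prom1 by 2.15 (SE 0.12) and Tspan8 by 0.69 (SE 0.10). Sinusoidal endothelial markers went both ways: 5 of 12 rose and 7 fell, with the median at percentile 10.95. The list had a mean shift of −0.0076 that did not pass (adjusted exact p = 0.835) except with arrays centred on their medians (−0.15, adjusted exact p = 0.00588). Lyve1 rose by 1.14 (SE 0.075) and Clec4g fell by 0.85 (SE 0.057).

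**Figure D3:**
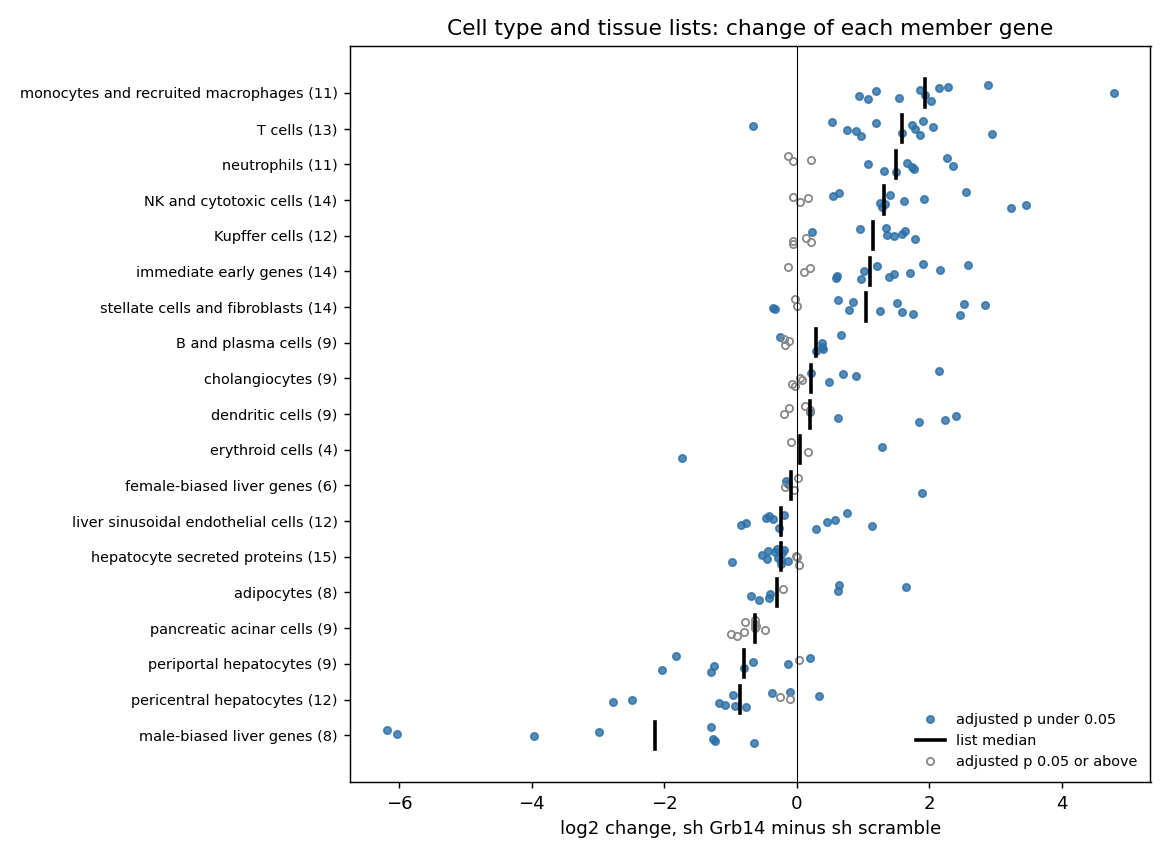
Log2 change, sh Grb14 minus sh scramble (horizontal axis), of each measured member (points) of the 19 cell type and tissue lists (rows, with the number of measured genes), drawn as for the pathway lists. Medians run from 1.94 for monocytes and recruited macrophages to −2.14 for male-biased liver genes.

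Liver genes that are higher in males fell in all 8 measured cases. Slco1a1 and Hsd3b5, the largest falls of the data set, belong to this list, whose median change was −2.14 and mean shift −2.95 (percentile 0; adjusted exact p = 0.00294; adjusted p = 0.141 with an estimated correlation). Female-biased genes had no common direction: 1 of 6 measured rose, 2 fell and 3 did not pass, with a mean shift of 0.23 (adjusted exact p = 0.00294) against a median of −0.088 (percentile 47.8). Cyp2b9 rose by 1.89 (SE 0.24), and Sult3a1, at levels of 3.73 and 3.59 near the bottom of the scale, had a change of −0.14 (SE 0.038). The call of this list was lost with an estimated correlation (adjusted p = 0.982) and when arrays were centred on their medians (0.085, adjusted exact p = 0.152).

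Lists of blood and neighbouring tissue did not shift with all mice and genes in the test. Of 4 measured erythroid genes Slc4a1 rose by 1.28 (SE 0.10), Alas2 fell by 1.73 (SE 0.087) and 2 did not pass, with a mean shift of −0.091 (adjusted exact p = 0.270, percentile 69.12). The erythroid list passed without sh Grb14 6 (−0.14, adjusted exact p = 0.0437) and with arrays centred on their medians (−0.24, adjusted exact p = 0.0274). Of 8 measured adipocyte genes 3 rose, 4 fell and 1 did not pass (mean shift 0.078; adjusted exact p = 0.685; percentile 1.1). The lipid droplet gene Cidec rose by 1.65 (SE 0.17) and the regulator Pparg by 0.63 (SE 0.12). The adipocyte list passed without sh scramble 4 (0.21, adjusted exact p = 0.0247) and among the genes above the median of mean level (0.67, adjusted exact p = 0.00548). None of 9 pancreatic acinar genes passed limma's test or had an unadjusted p under 0.05, and the mean shift was −0.72 (adjusted exact p = 0.578). The median of this list still lay at percentile 0, so an extreme percentile can arise without a shifted list. Liver sh scramble 4 had a level of 12.06 in that list, against 6.85 to 8.38 in the other livers of its group, and without it the mean shift of the acinar list was 0.091 (adjusted exact p = 0.909).

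Mitochondrial and clock genes fell, in livers where markers of recruited macrophages and T cells shifted by 2.06 and 1.35. Periportal and pericentral hepatocyte genes shifted by −0.86 and −0.89 there. Hepatocyte secreted protein genes, near the top of the scale where changes can be compressed, shifted by −0.29. Ndufb9, a subunit of complex I, fell by 0.76 (SE 0.042), and Sdha and Sdhb, of complex II, fell by 0.66 (SE 0.034) and 0.63 (SE 0.042). Of 27 measured oxidative phosphorylation genes 24 fell, 1 rose and 2 did not pass, with a mean shift of −0.39 and percentile 1.51 (adjusted exact p = 0.00271; adjusted p = 0.163 with an estimated correlation). In the circadian clock list Hlf and Tef, PAR bZIP output factors, fell by 1.27 (SE 0.069) and 1.10 (SE 0.056), and Per3 fell by 0.95 (SE 0.057). Of 17 measured clock genes 14 fell, 1 rose and 2 did not pass, with a mean shift of −0.57 and percentile 0 (adjusted exact p = 0.00271; adjusted p = 0.148 with an estimated correlation). Among the falls were genes that peak at different times of day: Arntl by 0.56 and Clock by 0.44, and Dbp by 0.53 and Per2 by 0.97. They were named after their values were seen, so they do not decide whether clock phase differed.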

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

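Single mice stood apart from their own group in 26 of 318 Dixon tests of named genes and lists, where chance gives about 1 in 20. Of these, 10 fell on liver sh scramble 5, 4 on sh scramble 6, 4 on sh Grb14 2 and 3 on sh scramble 4. The tests of sh scramble 4 below were chosen only after its levels of acinar and adipocyte genes were seen, the further pancreas genes before their own values were looked at.

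Liver sh scramble 5 stood below the rest of its group in G6pc (12.77, against 13.10 to 13.24), Ppp1r3b (10.21, against 10.52 to 10.67), Cyp2b9 (5.53, against 6.57 to 7.16), the glycolysis and glycogen list (10.95, against 11.09 to 11.16) and the female-biased list (6.16, against 6.35 to 6.44). The same liver stood above it in Ces3b (12.85, against 12.50 to 12.62), Ccl3 (7.00, against 6.63 to 6.76), Sult3a1 (3.80, against 3.70 to 3.73), Klf6 (8.23, against 7.90 to 8.01) and the antigen processing and presentation list (10.21, against 9.90 to 10.01). Liver sh scramble 6 was low in Serpina4-ps1 (11.09, against 11.94 to 12.35) and high in Elovl3 (13.03, against 12.91 to 12.96), Tdo2 (13.10, against 12.98 to 13.02) and the stellate cell and fibroblast list (8.91, against 8.63 to 8.70). High values stood apart in sh scramble 3 for Pgm2 (8.47, against 8.16 to 8.26) and in sh scramble 2 for Ccl2 (7.84, against 7.55 to 7.65).

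Among the livers with less Grb14, sh Grb14 2 was low in Gpnmb (10.56, against 11.22 to 11.53), Lpl (11.58, against 11.85 to 11.94) and Mki67 (10.22, against 10.37 to 10.46) and high in Acss2 (10.52, against 9.97 to 10.14). Liver sh Grb14 1 was low in H2-DMa (11.01, against 11.22 to 11.28) and in the antigen processing and presentation list (11.19, against 11.35 to 11.38), and sh Grb14 4 was low in Slc37a4 (10.25, against 10.58 to 10.75).

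Liver sh scramble 4 had far higher levels of digestive enzyme genes than the others of its group: its mean over the pancreatic acinar list was 12.06 (against 6.85 to 8.38), over the adipocyte list 8.15 (against 7.20 to 7.51), and its level of Prom1 was 7.06 (against 6.68 to 6.75). An array of poor quality is argued against, since it stood apart in 0 other lists and correlated with each liver of its group with r between 0.990 and 0.993. Tissue next to the liver in the sample, pancreas with fat, is a candidate source: of 17 further pancreas genes that stand in none of the lists, 16 were at their highest in this mouse by over 1, Clps at 12.99 with the next liver at 9.72 and Zg16 at 12.52 with the next at 8.57. Over the acinar list, sh scramble 3 (8.38), sh Grb14 4 (8.30) and sh Grb14 6 (8.37) also lay above the other livers (6.52 to 7.22), by far less. Of 8 adipocyte genes 5 were at their highest in sh scramble 4, Adipoq at 7.25 with the next at 5.93, though Cidec and Pparg were not. No biological explanation was tested, since the labels give nothing else that sets this mouse apart.

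Among the 12146 probe sets without a listed gene, which no comparison used, 4462 (36.7%) passed limma's test with every probe set tested, 1755 higher and 2707 lower in sh Grb14 livers, with changes from 5.55 to −4.44.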

How the results depend on the processing

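The fall of Grb14 stayed past the test under every alternative run, with changes from −1.86 to −2.05. The count of genes lower rose from 7868 to 12940 with each array centred on its median of the tested genes, by whose construction every gene of the sh Grb14 arrays, which had the higher medians, moved down. With only the 9969 genes above the median of mean level it was 4051. Fewer genes were tested there, and 48.5% of those past the test were higher, against 39.5% with all genes. With every probe set on its own the count higher rose from 5144 to 7788, since 35556 were tested. The count changed at least 1.5-fold stayed within 1.5 times under every alternative, and leaving out each mouse gave 4923 to 5129 genes higher, 6883 to 8368 lower and 3689 to 3835 changed at least 1.5-fold. Lists lost most with an estimated correlation: 0 of 20 pathway lists and 1 of 19 cell type lists were called with camera, and 6 in each family at an unadjusted p under 0.05. The exact test called 17 to 18 pathway lists and 14 to 16 cell type lists under the other alternatives. Lists that had not shifted changed sign without passing: with median centring fatty acid oxidation and PPAR-alpha targets (−0.088), acute phase proteins (−0.088) and adipocytes (−0.0693), and with the mean of probe sets sinusoidal endothelial cells (0.016). Leaving out each mouse gave −0.025 to 0.013 for the endothelial list, above 0 without sh scramble 6 or sh Grb14 2, and −0.95 to 0.091 for the acinar list, above 0 without sh scramble 4. The female-biased list, called at 0.23, had −0.18 among the genes above the median of mean level, where fewer members are measured. Median centring also brought the endothelial (−0.15), erythroid (−0.24) and endoplasmic reticulum stress (−0.20) lists past the test. The adipocyte list passed without sh scramble 4 (0.21) and among the genes above the median of mean level (0.67), and the erythroid list without sh Grb14 6 (−0.14). Otherwise the cause was not tested. No paired analysis was possible because the labels give no pairing. Signal over background is not given in the table, so no detection call was made for dim genes.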

Other observations

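Of the 16 gene families examined after the data were seen, several of hepatocyte metabolism and defence had mostly falling members. Periportal and pericentral hepatocyte genes shifted by −0.86 and −0.89 in the same livers. Of 16 carboxylesterases, ester and lipid hydrolases, 13 fell and 1 rose (median −1.08), among them Ces3a, which fell by 3.48 (SE 0.18), and Ces1e, which fell by 3.25 (SE 0.13). Of 11 Ugt genes, which encode UDP-glycosyltransferases, 8 fell and 0 rose (median −1.35). All 6 terminal complement genes, which encode the membrane attack complex, fell, C8a by 2.62 (SE 0.14) and C8b by 2.56 (SE 0.14). All 3 measured major urinary protein genes fell. Of 23 Slc22a organic ion transporters 13 fell and 2 rose, with changes of −3.39 (SE 0.13) for Slc22a30 and 3.56 (SE 0.16) for Slc22a27. The sh scramble level of Slc22a27 (5.04) lies below the lower quartiles of those arrays, so its change can be understated. Each of these families had an exact permutation p of 0.00216, the smallest possible, and each kept its direction with arrays centred on their medians. The median of the Slc22a transporters lay at percentile 7.66 of matched random lists, within their range. With an estimated correlation, camera gave an unadjusted p of 0.0271 for carboxylesterases, 0.0388 for complement, 0.0266 for major urinary proteins, 0.118 for Ugt genes and 0.279 for Slc22a transporters. Members of these families other than complement are similar in sequence and can share signal.

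Most measured genes rose among mitotic kinesins, centromere proteins, annexins and cathepsins. Markers of recruited macrophages, T cells, and stellate cells and fibroblasts shifted by 2.06, 1.35 and 1.11 in the same livers. All 12 mitotic kinesins rose (median 1.81), Kif11 by 2.78 (SE 0.088), and 17 of 21 centromere proteins rose with 1 lower. Mmp12, a macrophage elastase, rose 14.4-fold (log2 3.85, SE 0.13) and Mmp13, a collagenase, rose by 3.27 (SE 0.099), among 22 matrix metalloproteinases of which 9 rose and 4 fell. Of 12 annexins 8 rose and 1 fell, Anxa2 by 3.08 (SE 0.087), and of 17 cathepsins 12 rose and 2 fell, Ctss by 2.0 (SE 0.075). Atp6v0d2, a subunit of the lysosomal proton pump, rose by 3.0 (SE 0.13), in a family of 21 with 7 higher and 6 lower. Tubb6 rose by 2.28 (SE 0.068), among 14 tubulins with 6 higher and 3 lower. Among 40 proteasome genes 19 rose and 6 fell. Each of these families had an exact permutation p of 0.00216, which 50.2% of random lists of 20 genes also reach. Median centring lowered the mean shift from 0.20 to 0.054 for the proton pump, from 0.17 to 0.019 for proteasome genes and from 0.38 to 0.23 for tubulins. The medians of the proton pump and tubulin families lay within the range of matched random lists, at percentiles 83.9 and 87.4. Camera with an estimated correlation gave an unadjusted p of 0.0277 for kinesins, 0.0494 for centromere proteins, 0.0367 for cathepsins, 0.0645 for annexins, 0.153 for metalloproteinases, 0.162 for tubulins, 0.277 for proteasome genes and 0.498 for the proton pump. Of 55 ribosomal protein genes 30 rose and 2 fell, with the median at percentile 99.9. Their mean shift of 0.11 (exact permutation p = 0.00216) turned to −0.034 with median centring, and camera with an estimated correlation gave an unadjusted p of 0.131. The mean shifts of collagens (exact permutation p = 0.400) and keratins (exact permutation p = 0.305) did not pass. Of 44 collagens 11 rose and 24 fell, with the median at percentile 0.550, and of 52 keratins 6 rose and 24 fell, with the median at percentile 29.25. Col1a1 rose by 1.76 (SE 0.066) and Col18a1 fell by 0.97 (SE 0.054), Krt34 fell by 0.46 (SE 0.077), and Krt8 and Krt18, keratins of hepatocytes and ducts, rose by 1.07 (SE 0.032) and 1.18 (SE 0.061).

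For the patterns below, the tests of scaling, of dilution, of the vectors and of hepatocyte genes in general were chosen only after the result was seen.

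The first pattern is the breadth of the difference, with 13012 genes past the test. Chance is argued against: 1 of 100 splits of the 12 mice drawn from 462 possible, the real one, gave as many genes. The highest other gave 7120. These splits cannot tell the hairpin from a batch that followed the groups. Scaling of the arrays as the cause of the changes of at least 1.5-fold is argued against, since in each of 10 equal groups of genes by mean level at least 15.1% of those changes went in the rarer direction, while for smaller changes it stays open. Dilution of hepatocyte RNA by RNA of other cells is argued against as the cause of the falls of over 4-fold, since 44 hepatocyte genes outside the male-biased list, with sh scramble means between 9 and 13, had a lower quartile of −1.26. The 44 genes include members of pathway lists whose falls are themselves in question. Their extremes, −4.51 and 1.71, are the lowest change of the cytochrome P450 list (Cyp2c54) and the highest of the gluconeogenesis list. For falls of 2- to 4-fold the rule chosen does not decide, because the median of the 44 genes was −0.86 and a fall of 1 lies within their quartiles. Dilution alone would lower all of them alike, but 28 of the 44 fell by under 1. Their upper quartile was −0.34 and their highest change 1.71. These values argue against dilution alone as the cause of the falls of 2- to 4-fold. A share of dilution in such falls cannot be told apart from lower expression. A difference between the 2 adenovirus preparations or their dose, or other targets of the hairpin, cannot be told apart from the loss of Grb14, because each group received 1 vector, and the interferon response list, which a vector can also move, shifted by 1.21; no test here decides whether the loss of Grb14 is the source of the breadth.

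A second pattern is the fall of male-biased liver genes, with a median of −2.14 over 8 genes. Mice of different sex in the 2 groups are argued against, since the 3 measured Y-linked genes Eif2s3y, Kdm5d and Uty had a median difference of −0.16 and Xist one of −0.065. Whether the list merely follows hepatocyte genes in general stays open. Of 10000 random lists of the same size from 72 hepatocyte genes, which also include pathway list members, 0.01% had a median as low. The 2.5 percentile of these random lists was −1.19. These draws take genes independently, while the list members moved together (estimated correlation 0.608), so 0.01% overstates the contrast. The 72 genes had a median of −0.544, against −0.86 for the 44 hepatocyte genes of the first pattern, which eases the comparison. The list median still lay below the lower quartile of those 44 genes, −1.26. Camera with the estimated correlation, against all other genes, gave an adjusted p of 0.141. No test here decides whether the male pattern of the liver was lost selectively, and the vectors stay open here as well.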
